A study of Homo sapiens with 12 samples.

How the data were processed

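The 12 samples were RNA libraries of MV4-11 cells after 72 h in vehicle, 250 µM LAA, 1 µM ATRA or both, with 3 libraries per group. Groups, doses and replicate numbers were taken from the sample labels. Per the labels' protocols, the cells were grown in RPMI medium with 10% FBS, RNA was extracted with RNeasy Plus Mini columns, polyadenylated RNA was captured on poly-T beads, and libraries were made with random hexamers and the NEBNext Ultra II kit. The strand that the libraries preserve was not stated. The labels give the cells the cell type tag macrophage, although the line is a leukemia line of monocytic character.

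The authors deposited a table of estimated counts per gene (61125 genes), not normalized between libraries, of which 24.0% of cells were not whole numbers (tolerance 0), and the submitters' processing notes name Salmon 1.8.0, DESeq2 1.42.0 and GRCh38 without a role or an order. The authors also deposited a table of FPKM values of the same libraries, scaled by library size and gene length, and how these were computed was not stated. The gene length implied by the ratio of both deposited tables differed between libraries. The annotation behind the tables was not stated.

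The estimated counts were rounded to whole numbers. Genes were kept by the filterByExpr function of edgeR 4.0.16 on the groups (minimum count 10, minimum total 15), which left 16580 of 61125. Library sizes were scaled by TMM. A quasi-likelihood model with 1 coefficient per group was fitted to all 12 libraries with edgeR, without a replicate block, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The 6 comparisons were LAA against vehicle, ATRA against vehicle, LAA+ATRA against vehicle, LAA+ATRA against ATRA, LAA+ATRA against LAA, and the interaction, which is the ascorbate effect with ATRA minus the ascorbate effect without it. A gene beyond both single agents was called with the same sign in the 3 comparisons that involve LAA+ATRA and another group. CPM used TMM-scaled library sizes, and principal components used log2 CPM with a prior count of 2. The biological coefficient of variation was 0.091.

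Lists of 26 gene groups were written from general knowledge before the data were examined, as were the comparisons, the tests, the rule for naming genes and most alternatives. The 24 lists with at least 5 tested members were tested with camera in limma 3.58.1 (preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the lists within a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance 1 way, were alternatives. The lists were retinoic acid targets, primary granule genes, late neutrophil genes, monocyte and macrophage genes, NADPH oxidase genes, antigen presentation and dendritic cell genes, lymphoid genes, erythroid and megakaryocyte genes, and MLL fusion and leukemia stem cell genes. Further lists were MYC and ribosome biogenesis genes, cell cycle genes, BCL2 family genes, DNA methylation machinery genes, germline genes silenced by DNA methylation, ascorbate transport and hydroxylase genes, and HIF targets. The last were NRF2 targets, iron handling genes, type I interferon response genes, NF-kB and inflammatory cytokine genes, cholesterol synthesis genes, LXR and PPAR targets, ATF4 and unfolded protein response genes, FLT3, STAT5 and MAPK output genes, and mitochondrially encoded genes. The result of 1 further list is not reported here.

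Genes were named by a rule with 3 parts. The first took, in each comparison, the 6 largest rises and 6 largest falls among called genes with a mean of at least 2 CPM, a gene symbol and, for a pair of groups, no overlap between the groups, which chance gives for 10% of genes with 3 libraries against 3. The second took up to 4 called members of each list with the smallest p. The third was a panel of retinoid, myeloid, leukemia and TET genes. Symbols came from the deposited table and, for 8199 further identifiers, from a separate reference of gene names matched by gene identifier. GENCODE release 29 gave the locations on GRCh38. Among the genes tested, 1727 had no symbol.

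The alternatives were DESeq2 1.42.0, RLE size factors, no count filter, a filter of at least 1 CPM in 3 libraries, a fit of only the groups compared, a further limit of a log2 fold change of at least 1 in size, the replicate number as a block, limma on log2 FPKM with pseudocounts of 1 and 0.1 and with and without a minimum mean of 0.5 FPKM, and the omission of each library in turn. Counts of the alternatives in which a gene stayed called leave out the limit of a log2 fold change of at least 1, since it removes genes by size and does not test them again. An offset for gene length per library and the omission of LAA replicate 7 from comparisons that do not use it were added after the data were seen. Other splits of the libraries were counted, 10 for each pair of groups and 100 drawn for the interaction. Libraries were simulated from the fitted means and dispersions in 20 data sets without an ascorbate effect, with each gene drawn independently. The analysis was tested on simulated data with known changes in 6 runs of 16580 genes. It recovered 35.3% of 1.25-fold, 74.3% of 1.5-fold, 86% of 2-fold and 97.7% of 4-fold changes, and 68 of 948 calls (7.17%) were false, with the same spread assumed in all groups. The changes were placed only in genes with mean counts well above the filter's minimum. The recovery rates therefore do not cover genes with few counts. Of the gene lists, 1 of 1 moved by 1.25-fold was called and 0 of 23 unchanged ones were. Genes were drawn independently here too, so this test does not cover false list calls that come from correlation between members.

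Libraries held between 35.6 and 59.5 M estimated counts. Floors for genes without counts, 3 counts over the group, cover counting error only. SOD2 could not be matched to an identifier and was left out of its list. R 4.3.3, Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 were used.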

Results

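Polyadenylated RNA was sequenced from MV4-11, a human acute myeloid leukemia line of monocytic character with an MLL rearrangement and an internal tandem duplication of FLT3. The cells were kept for 72 h in vehicle (PBS with DMSO), in 250 µM L-ascorbic acid (LAA), in 1 µM all-trans retinoic acid (ATRA) or in both compounds. ATRA is a ligand of the retinoic acid receptors that drives myeloid differentiation. Ascorbate is a cofactor of iron-dependent dioxygenases, which include the TET enzymes. The title of the series concerns the joint action of both compounds against myeloid leukemia through TET2. Each of the 4 groups held 3 libraries, which the labels number 5, 6 and 7. The total estimated counts (M, mega) were 59.5 M, 42.7 M and 45.9 M in vehicle and 39.7 M, 35.6 M and 36 M in LAA. They were 44.0 M, 47.6 M and 37.9 M in ATRA, and 38.2 M, 43.0 M and 40.4 M in LAA+ATRA. After a filter on low counts, 16580 genes were tested in 6 comparisons. Genes were called at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Log2 fold changes are given ± SE and CPM ± SD, with n = 3 per group. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

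Libraries with and without ATRA separated on the first principal component of log2 CPM, which held 48.1% of the variance. Scores ran from -56.5 to -46.4 without ATRA and from 48.6 to 53.7 with it. LAA replicate 7 stood apart on the second component, which held 8.77% of the variance, with a score of 67.1 against -24.0 to 5.24 in the other 11 libraries. The median SD of log2 CPM within a group was 0.14 in vehicle, 0.16 in LAA, 0.09 in ATRA and 0.11 in LAA+ATRA. Genes of the mitochondrial genome took 3.93% ± 0.301 of the counts in vehicle, 4.66% ± 0.452 in LAA, 4.41% ± 0.102 in ATRA and 4.11% ± 0.194 in LAA+ATRA (SD, n = 3). The highest share, 5.19%, was that of LAA replicate 7.

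**Figure D1:**
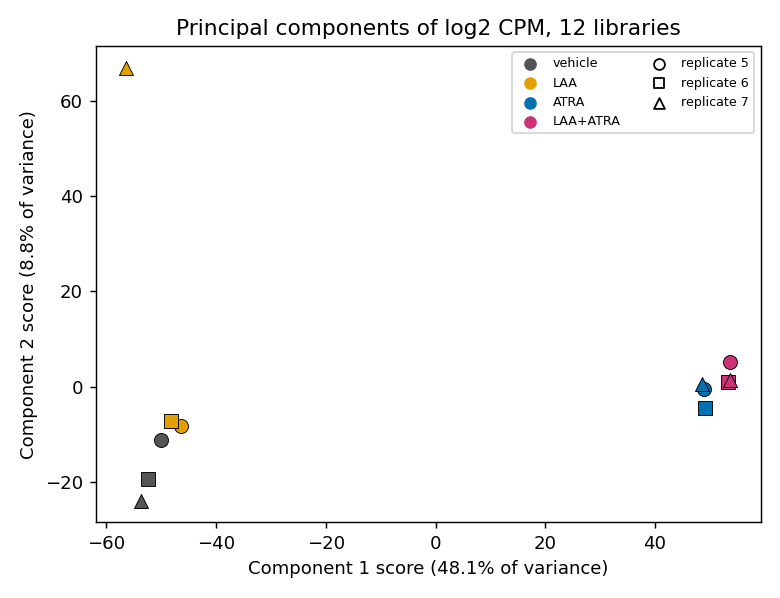
Scores of the 12 libraries on the first (horizontal) and second (vertical) principal component of log2 CPM, without units, colored by group and shaped by replicate number. The ATRA and LAA+ATRA libraries lie between 48.6 and 53.7 on the first component and all others between -56.5 and -46.4, and LAA replicate 7 lies alone at 67.1 on the second.

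The first comparison asked how ATRA alone changed the cells. ATRA raised retinoic acid target genes, phagocyte oxidase genes and most of the tested genes of the monocyte and late neutrophil lists. It lowered MYC and the serine synthesis genes PSAT1 and PHGDH. TGM2, a transglutaminase gene induced by retinoids, went from 0.0923 ± 0.0800 to 95.0 ± 2.92 CPM (log2 fold change 9.89 ± 0.19, edgeR adjusted p = 1.45e-14). The ectoenzyme gene CD38 rose from 12.2 ± 0.964 to 273 ± 3.75 CPM. ITGAM, the CD11b integrin chain of mature myeloid cells, rose from 32.5 ± 2.33 to 199.8 ± 3.42 CPM. MYC fell from 361 ± 13.6 to 156 ± 4.45 CPM (log2 fold change -1.21 ± 0.05, edgeR adjusted p = 2.41e-11).

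Of the 16580 genes, edgeR called 8210, 4132 higher and 4078 lower with ATRA, and 1856 of them changed at least 2-fold (913 higher and 943 lower). Among called genes with a symbol, a mean of at least 2 CPM and no overlap between the groups, the largest rises were those of TGM2, the eosinophil chemoattractant gene CCL24 (log2 fold change 8.20 ± 0.38), the potassium channel gene KCNH4 (7.50 ± 0.38), DAAM2 (7.40 ± 0.17) and the chemokine receptor gene CXCR5 (7.18 ± 0.49). ARL14EPL had no count in any vehicle library and 5.24 ± 0.558 CPM in ATRA. Against a floor of 3 counts over the vehicle group it was at least 269-fold higher. Under the same limits the largest falls were those of IGLL1, a surrogate light chain gene of B-cell precursors (-7.42 ± 0.26), LINC01226 (-5.11 ± 0.32), TCEA3 (-4.51 ± 0.38) and the serine protease gene HTRA1 (-4.16 ± 0.24). The BMP antagonist gene NOG (-3.72 ± 0.14) and NRXN3 (-3.71 ± 0.21) came next. IGLL1 belongs to a family of similar sequences, so reads shared with its relatives make its level uncertain. TGM2 (ENSG00000198959.12) lies on chromosome 20 of GRCh38 from 38127387 to 38166578 on the minus strand.

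Of 18 tested retinoic acid target genes 14 rose and 2 fell, the same counts as adjusted over the list alone. Camera set the list apart from the other genes (adjusted p = 2.26e-33; adjusted p = 0.00023 with an estimated correlation). THBD, encoding thrombomodulin, rose by 6.11 ± 0.08 (log2), the retinal reductase gene DHRS3 by 3.69 ± 0.09 and the receptor gene RARB by 3.76 ± 0.30. RARA differed by 0.11 ± 0.09 (edgeR adjusted p = 0.346), and ASB2 fell by 0.99 ± 0.08. All 6 NADPH oxidase genes rose, also when adjusted over the list alone (camera adjusted p = 2.12e-17; adjusted p = 0.00226 with an estimated correlation). Among them were CYBB (4.18 ± 0.09) and NCF1 (5.15 ± 0.14), whose reads may be shared with near-identical copies.

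Among 27 tested monocyte and macrophage genes 18 rose and 7 fell, the same counts as adjusted over the list alone (camera adjusted p = 6.79e-14; adjusted p = 0.00334 with an estimated correlation). The lysosomal protease gene CTSD (log2 fold change 2.32 ± 0.05), the chemokine receptor gene CCR1 (2.73 ± 0.07) and CD68 (2.02 ± 0.06) were among those that rose. Of 17 tested late neutrophil genes 12 rose and 3 fell, the same counts as adjusted over the list alone (camera adjusted p = 1.25e-07; adjusted p = 0.00454 with an estimated correlation). S100A9 rose by 3.45 ± 0.13, CXCR2 by 2.04 ± 0.07 and CSF3R by 1.51 ± 0.06. The late neutrophil list has 29 members, and those not tested were under the count filter. Among these, LTF had 30, PGLYRP1 10 and OLFM4 2 counts over all 12 libraries. LCN2, CRISP3, ALPL, FCGR3B and MME had 0, so the list does not show full neutrophil maturation. Of 12 tested primary granule genes 10 rose and 1 fell, the same counts as adjusted over the list alone (camera adjusted p = 1.98e-12; adjusted p = 0.0709 with an estimated correlation). BPI rose by 3.48 ± 0.11, PRTN3 by 2.43 ± 0.07 and ELANE by 1.95 ± 0.07. The myeloid transcription factor genes CEBPE (1.01 ± 0.09), SPI1 (0.74 ± 0.07) and CEBPB (0.61 ± 0.07) rose too. CD14, MPO, CYP26A1 and CYP26B1 were under the count filter, with 22, 71, 17 and 0 counts over all 12 libraries. Small changes in them were not detectable at this depth.

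Of 14 tested LXR and PPAR target genes, which act in lipid uptake and synthesis, 11 rose and 0 fell, the same as adjusted over the list alone (camera adjusted p = 3.16e-16; adjusted p = 0.000305 with an estimated correlation). They included CD36 (log2 fold change 2.55 ± 0.06), PLTP (1.91 ± 0.06) and SREBF1 (1.29 ± 0.04). Of 32 tested type I interferon response genes 24 rose and 3 fell (25 and 3 adjusted over the list alone). The camera adjusted p of this list was 1e-11 (adjusted p = 0.127 with an estimated correlation), and OAS1 rose by 2.94 ± 0.13 and SAMD9L by 2.40 ± 0.14. Of 22 tested ATF4 and unfolded protein response genes 5 rose and 13 fell (7 and 13 adjusted over the list alone), with camera adjusted p = 7.76e-07 (adjusted p = 0.127 with an estimated correlation). The serine synthesis genes PSAT1 and PHGDH fell by 2.72 ± 0.06 and 2.09 ± 0.06, MTHFD2 of mitochondrial folate metabolism fell by 1.76 ± 0.06, and ATF4 itself fell by 1.72 ± 0.06. Of 26 tested MYC and ribosome biogenesis genes 2 rose and 17 fell, the same as adjusted over the list alone (camera adjusted p = 0.00201; adjusted p = 0.352 with an estimated correlation). NPM1 of this list fell by 0.84 ± 0.06.

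Of 13 mitochondrially encoded genes 12 rose and 0 fell (13 adjusted over the list alone), MT-CYB by 0.76 ± 0.10 (log2), with camera adjusted p = 0.00385 (adjusted p = 0.495 with an estimated correlation). Of 14 tested iron handling genes 7 rose and 3 fell (8 and 3 adjusted over the list alone), with camera adjusted p = 0.0272 (adjusted p = 0.127 with an estimated correlation). With an offset for each library's gene lengths the camera adjusted p of that list was 0.103. Of 10 tested lymphoid genes 1 rose and 6 fell, the same as adjusted over the list alone (camera adjusted p = 0.0113; adjusted p = 0.0709 with an estimated correlation).

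Other lists held genes that moved both ways, and camera did not set them apart from the remaining genes. Of 30 tested cell cycle genes 8 rose and 16 fell (camera adjusted p = 0.271), with RRM2 at 0.87 ± 0.05, MKI67 at 0.34 ± 0.10 and CDK1 at -0.72 ± 0.08 (log2). Of 21 tested MLL fusion and leukemia stem cell genes 4 rose and 6 fell (camera adjusted p = 0.428). HOXA9 fell by 0.79 ± 0.06 and CDK6 fell by 0.80 ± 0.09. Of 15 tested BCL2 family genes 7 rose and 5 fell (camera adjusted p = 0.828), with the survival genes MCL1 at 0.76 ± 0.06 and BCL2 at -1.28 ± 0.08. Of 27 tested HIF target genes 6 rose and 13 fell (camera adjusted p = 0.37), and VEGFA fell by 1.75 ± 0.07. Of 12 antigen presentation and dendritic cell genes 1 rose and 5 fell (camera adjusted p = 0.257), with CIITA at -1.67 ± 0.17. Of 18 NRF2 target genes 6 rose and 5 fell (camera adjusted p = 0.37), and of 16 NF-kB and inflammatory cytokine genes 4 rose and 6 fell (camera adjusted p = 0.365). Of 22 cholesterol synthesis genes 10 rose and 2 fell (camera adjusted p = 0.0969; 0.0423 with the length offset). Of 22 FLT3, STAT5 and MAPK output genes 9 rose and 5 fell (camera adjusted p = 0.0969). Of 14 ascorbate transport and ascorbate-dependent hydroxylase genes 5 rose and 3 fell (camera adjusted p = 0.531). Adjusted over the list alone, 7 HIF target genes rose and 13 fell, 6 ascorbate genes rose and 3 fell, and the other 8 pairs of counts were the same. Only 1 of 30 germline genes silenced by DNA methylation and 4 of 20 erythroid and megakaryocyte genes were expressed enough to be tested. SOHLH2 fell by 1.58 ± 0.22, and ITGA2B rose by 1.85 ± 0.49.

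Of 18 tested DNA methylation machinery genes 6 rose and 5 fell with ATRA (7 and 5 adjusted over the list alone; camera adjusted p = 0.607). TET2 was at 14.95 ± 1.82 CPM in vehicle, 13.2 ± 4.19 in LAA, 20.2 ± 1.62 in ATRA and 19.9 ± 2.45 in LAA+ATRA. Its log2 fold change with ATRA, 0.43 ± 0.17, did not pass (edgeR adjusted p = 0.0515), nor did that of TET3, 0.20 ± 0.13 (edgeR adjusted p = 0.235). TET1 fell by 0.72 ± 0.24 (edgeR adjusted p = 0.0219), a call kept in 10 of 15 alternatives with the limit on the size of the change left aside, and IDH1 rose by 0.75 ± 0.05. Of 114 named genes called in this comparison, 110 were called in every alternative that could test them, again without the limit on size.

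The next comparison asked what ascorbate did alone. Its effects were small. Cholesterol synthesis genes and cell cycle genes were the lists that camera also called higher with an estimated correlation, and LINC03040, PRTN3, CPXM1, LYZ, INSIG1 and SCD were the named genes called in at least 15 of 16 alternatives, the limit on the size of the change left aside. LINC03040, annotated as protein coding in GENCODE release 29, rose from 30.2 ± 1.96 to 52.1 ± 2.70 CPM (log2 fold change 0.79 ± 0.06, edgeR adjusted p = 6.2e-05) and was called in all 16 alternatives other than the limit of a log2 fold change of at least 1. PRTN3, encoding the granule protease proteinase-3, rose from 328 ± 30.1 to 525 ± 54.3 CPM (0.68 ± 0.07, edgeR adjusted p = 0.000564). CPXM1, encoding a carboxypeptidase-like protein, rose from 1.8 ± 0.313 to 5.01 ± 0.619 CPM (1.47 ± 0.15, edgeR adjusted p = 0.000564). LYZ, encoding lysozyme, rose by 0.52 ± 0.06, INSIG1, a regulator of sterol synthesis, by 0.42 ± 0.05, and SCD, a fatty acid desaturase gene, by 0.46 ± 0.05 (log2). PRTN3, CPXM1, LYZ, INSIG1 and SCD were each called in 15 of these 16 alternatives.

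EdgeR called 325 genes, 232 higher and 93 lower, and 19 of them changed at least 2-fold. Under the limits on symbol, CPM and overlap given above, other large rises were those of the class II genes HLA-DRB5 (log2 fold change 0.90 ± 0.16) and HLA-DRB1 (0.70 ± 0.11), whose reads may be shared with related genes. ANG (0.87 ± 0.18), KIF17 (0.86 ± 0.18) and the heme oxygenase gene HMOX1 (0.78 ± 0.16) rose as well. Under the same limits the largest falls were those of NRXN3 (-0.93 ± 0.18), PCGF3-AS1 (-0.85 ± 0.19), TMEM161B-DT (-0.82 ± 0.14), the readthrough transcript STIMATE-MUSTN1 (-0.75 ± 0.17), ONECUT2 (-0.73 ± 0.16) and RN7SL2 (-0.72 ± 0.15). PCGF3-AS1 and TMEM161B-DT are annotated as antisense to other genes, STIMATE-MUSTN1 overlaps the genes it joins and RN7SL2 has many copies, so their counts are uncertain. The survival gene BCL2 fell by 0.53 ± 0.07 and the cystine transporter gene SLC7A11 fell by 0.48 ± 0.10. BCL2, SLC7A11, ANG, KIF17, HMOX1 and the genes with the largest falls were not called with the length offset. Nor were they called with limma on FPKM with a pseudocount of 1. HLA-DRB5 and HLA-DRB1 were called with that limma fit but not with the length offset. MYC (0.03 ± 0.05, edgeR adjusted p = 0.747), CD38 (0.17 ± 0.07, adjusted p = 0.23), ITGAM (0.15 ± 0.06, adjusted p = 0.236) and TET2 (-0.18 ± 0.18, adjusted p = 0.637) were not called.

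Of 22 tested cholesterol synthesis genes 14 rose and 0 fell with ascorbate alone (18 adjusted over the list alone; camera adjusted p = 1.97e-24; adjusted p = 0.0212 with an estimated correlation). HMGCS1, an early enzyme gene of the pathway, rose from 90.6 ± 5.61 to 125 ± 10.3 CPM, FDFT1 by 0.39 ± 0.06 and DHCR7 by 0.32 ± 0.05 (log2). Of 30 tested cell cycle genes 6 rose and 0 fell (21 adjusted over the list alone; camera adjusted p = 5.94e-15; adjusted p = 0.0462 with an estimated correlation). RRM2 rose by 0.36 ± 0.05 and MCM5 by 0.35 ± 0.06. Of 13 mitochondrially encoded genes 10 rose (13 adjusted over the list alone; camera adjusted p = 1.83e-19; adjusted p = 0.0646 with an estimated correlation). MT-ND2 rose by 0.53 ± 0.09, and the median of the list was 0.41 with and 0.27 without LAA replicate 7. Of 12 tested primary granule genes 4 rose (9 adjusted over the list alone; camera adjusted p = 1.84e-11; adjusted p = 0.0943 with an estimated correlation), CTSG by 0.38 ± 0.06 and ELANE by 0.36 ± 0.06.

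Of 14 iron handling genes 3 rose with ascorbate alone (4 adjusted over the list alone; camera adjusted p = 0.00145; adjusted p = 0.0646 with an estimated correlation). The transferrin receptor gene TFRC was among them (0.47 ± 0.05), and the camera adjusted p of the list was 0.14 with the length offset. Of 17 late neutrophil genes 3 rose (4 adjusted over the list alone; camera adjusted p = 0.00419; adjusted p = 0.0646 with an estimated correlation), with camera adjusted p = 0.0553 without LAA replicate 7. Of 18 NRF2 target genes 2 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00723; adjusted p = 0.252 with an estimated correlation). Of 12 antigen presentation and dendritic cell genes 1 rose (3 adjusted over the list alone; camera adjusted p = 0.022; adjusted p = 0.0892 with an estimated correlation), with camera adjusted p = 0.059 without vehicle replicate 5.

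The number of genes called with LAA alone was 13 (12 higher and 1 lower) with the length offset, 28 (27 higher and 1 lower) with limma on FPKM, 942 with DESeq2, 1255 (521 higher and 734 lower) without a count filter, and 1, LINC03040, when only these 6 libraries were fitted. It was 1204 without vehicle replicate 5, 84 without vehicle replicate 6, 39 (36 higher and 3 lower) without vehicle replicate 7 and 202 without LAA replicate 6. The SE and adjusted p given for LAA alone rest on a variance shared with the ATRA groups. The median SD of log2 CPM was lower in those groups, so these SE and adjusted p may be too small.

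**Figure D2:**
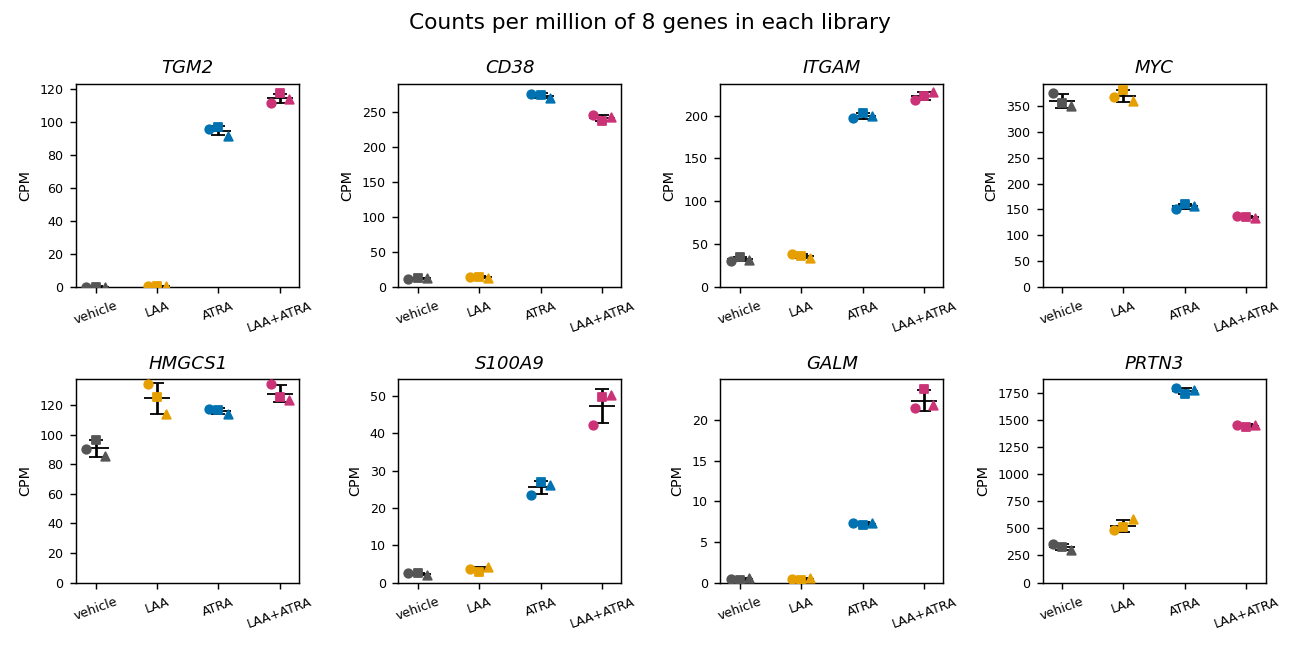
CPM (vertical axes, linear from 0) of 8 genes in each of the 12 libraries, by group (horizontal axes); points are libraries, long horizontal lines group means and error bars 1 SD (n = 3). TGM2, CD38 and ITGAM are high and MYC is low in both groups with ATRA, S100A9 and GALM are highest in LAA+ATRA, and PRTN3 is at 328 CPM in vehicle and 525 CPM in LAA.

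The third comparison set the combination against vehicle. It changed much the same genes as ATRA did. TGM2 reached 115 ± 2.86 CPM, and S100A9, encoding a subunit of calprotectin, went from 2.33 ± 0.330 to 47.5 ± 4.54 CPM. MYC fell to 135 ± 1.5 CPM and BCL2 from 62.0 ± 2.54 to 21.8 ± 1.01 CPM. ASNS, encoding asparagine synthetase, fell from 23.1 ± 2.08 to 1.38 ± 0.865 CPM.

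EdgeR called 8360 genes, 4214 higher and 4146 lower with the combination. Of these, 7270 were also called with ATRA alone in the same direction, 3734 higher and 3536 lower. Independent lists would share 1050 and 1020, and part of the excess may come from the shared vehicle libraries. Among the largest changes under the limits on symbol, CPM and overlap were those of CCL24 (log2 fold change 8.79 ± 0.37), KCNH4 (7.57 ± 0.38), IGLL1 (-7.61 ± 0.27), NRXN3 (-5.01 ± 0.24), the lincRNA gene IGFL2-AS1 (-4.20 ± 0.21) and ASNS (-4.06 ± 0.30). The strand that the libraries preserve was not stated, so reads from the other strand make the counts of IGFL2-AS1 uncertain. ARL14EPL was at least 379-fold higher than a floor of 3 counts over the vehicle group. CEBPE rose by 1.31 ± 0.09 and ITGAM by 2.78 ± 0.07, while TET2 differed by 0.41 ± 0.17 (edgeR adjusted p = 0.0618).

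By camera, 5 lists stayed called with an estimated correlation, at adjusted p from 0.000204 to 0.00272, and their counts were the same adjusted over the list alone. They were retinoic acid target genes (13 higher and 2 lower of 18), NADPH oxidase genes (6 higher of 6), LXR and PPAR target genes (11 higher and 1 lower of 14), monocyte and macrophage genes (19 higher and 6 lower of 27) and late neutrophil genes (12 higher and 2 lower of 17). Type I interferon response genes had 27 higher and 2 lower of 32 (29 and 2 adjusted over the list alone; camera adjusted p = 2.29e-14; adjusted p = 0.0934 with an estimated correlation). Cholesterol synthesis genes had 18 higher and 1 lower of 22, the same as adjusted over the list alone (camera adjusted p = 0.00221; adjusted p = 0.293 with an estimated correlation). MYC and ribosome biogenesis genes had 2 higher and 18 lower of 26, the same as adjusted over the list alone (camera adjusted p = 0.000195; adjusted p = 0.235 with an estimated correlation).

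The comparison of the combination with ATRA alone asked what ascorbate added to ATRA. It raised GALM, a galactose metabolism gene, ALAS1, which encodes the rate-limiting enzyme of heme synthesis in most cells, and the calprotectin gene S100A9. GALM went from 7.25 ± 0.138 to 22.4 ± 1.26 CPM (log2 fold change 1.63 ± 0.13, edgeR adjusted p = 1.76e-05), with 0.449 ± 0.126 CPM in vehicle and 0.461 ± 0.0980 CPM in LAA. ALAS1 went from 301 ± 3.09 to 457 ± 2.96 CPM (0.60 ± 0.04, edgeR adjusted p = 1.17e-05). S100A9 went from 25.6 ± 1.75 to 47.5 ± 4.54 CPM (0.89 ± 0.11, edgeR adjusted p = 0.00186). The amino acid transporter gene SLC7A5 fell by 0.39 ± 0.05 (edgeR adjusted p = 0.00519) and was named after its values were seen.

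EdgeR called 42 genes, 24 higher and 18 lower, of which 6 changed at least 2-fold. Under the limits on symbol, CPM and overlap, other leading rises were those of ITLN1, S100A8 (log2 fold change 1.36 ± 0.24), the purinergic receptor gene P2RY13 (0.98 ± 0.09) and FCGR2B, an inhibitory Fc receptor gene (0.81 ± 0.08). The leading falls under these limits were those of FLRT1 (-0.79 ± 0.12), UNC5A (-0.62 ± 0.11), POP1 (-0.57 ± 0.10), the IgE receptor gene FCER2 (-0.57 ± 0.08), the lincRNA gene BCAN-AS1 (-0.47 ± 0.08), whose counts carry the same doubt about the strand as those of IGFL2-AS1, and SEZ6L2 (-0.43 ± 0.07). With the limit on the size of the change left aside, GALM, ALAS1 and FCGR2B were called in all 17 alternatives, P2RY13 in 16, S100A9 in 15, ITLN1 in 10 and S100A8 in 7. The 6 genes with the leading falls were called in 6 to 9 of them. TGM2 (0.27 ± 0.09, edgeR adjusted p = 0.384), CD38 (-0.18 ± 0.06, adjusted p = 0.364), MYC (-0.21 ± 0.05, adjusted p = 0.108) and TET2 (-0.02 ± 0.17, adjusted p = 0.996) were not called. GALM (ENSG00000143891.17) lies on chromosome 2 of GRCh38 from 38665910 to 38741237, and ALAS1 (ENSG00000023330.15) on chromosome 3 from 52198086 to 52214327, both on the plus strand.

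Late neutrophil genes lay higher with the combination than with ATRA by camera (adjusted p = 5.05e-09; adjusted p = 0.00738 with an estimated correlation). S100A8 and S100A9 were the 2 of 17 called, and adjusted over the list alone 7 were higher and 1 was lower. Iron handling genes had 2 of 14 higher, the same adjusted over the list alone (camera adjusted p = 0.00403; adjusted p = 0.152 with an estimated correlation). They were FBXL5, an iron-sensing ubiquitin ligase subunit gene (0.34 ± 0.05), and TFRC (0.27 ± 0.05). Camera also called 5 lists higher and 3 lower in which no single member was called. Cholesterol synthesis genes had a median of 0.14 (6 higher adjusted over the list alone; camera adjusted p = 8.58e-11; adjusted p = 0.129 with an estimated correlation). Type I interferon response genes had a median of 0.24 (6 higher adjusted over the list alone; camera adjusted p = 2.69e-07; adjusted p = 0.275 with an estimated correlation), with camera adjusted p = 0.0711 without LAA+ATRA replicate 7. NRF2 target genes had a median of 0.07 (3 higher adjusted over the list alone; camera adjusted p = 0.00188; adjusted p = 0.275 with an estimated correlation), with camera adjusted p = 0.0507 with the length offset. Retinoic acid target genes (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0247; adjusted p = 0.275 with an estimated correlation) and lymphoid genes (0 adjusted over the list alone; camera adjusted p = 0.0296; adjusted p = 0.197 with an estimated correlation) both had camera adjusted p = 0.0711 without LAA+ATRA replicate 7. Primary granule genes lay lower (4 lower adjusted over the list alone; camera adjusted p = 0.0247; adjusted p = 0.558 with an estimated correlation), with camera adjusted p = 0.222 without LAA+ATRA replicate 5. MYC and ribosome biogenesis genes lay lower (1 lower adjusted over the list alone; camera adjusted p = 0.00403; adjusted p = 0.364 with an estimated correlation), with camera adjusted p = 0.0956 with the length offset. Mitochondrially encoded genes lay lower (0 adjusted over the list alone; camera adjusted p = 0.0048; adjusted p = 0.551 with an estimated correlation), with camera adjusted p = 0.0711 without LAA+ATRA replicate 7. ATF4 and unfolded protein response genes had a median of -0.09 and 1 of 22 lower (1 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.000228; adjusted p = 0.275 with an estimated correlation).

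The count of 42 became 177 with DESeq2, 166 when LAA replicate 7 was kept out of the shared fit and 418 when only these 6 libraries were fitted, and each of these sets held all 42 genes. It fell to 7 (5 higher and 2 lower) with the length offset, to 13 (10 higher and 3 lower) with limma on FPKM, and to 11, 6 and 10 without ATRA replicates 5, 6 and 7 and 15, 5 and 16 without LAA+ATRA replicates 5, 6 and 7.

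**Figure D3:**
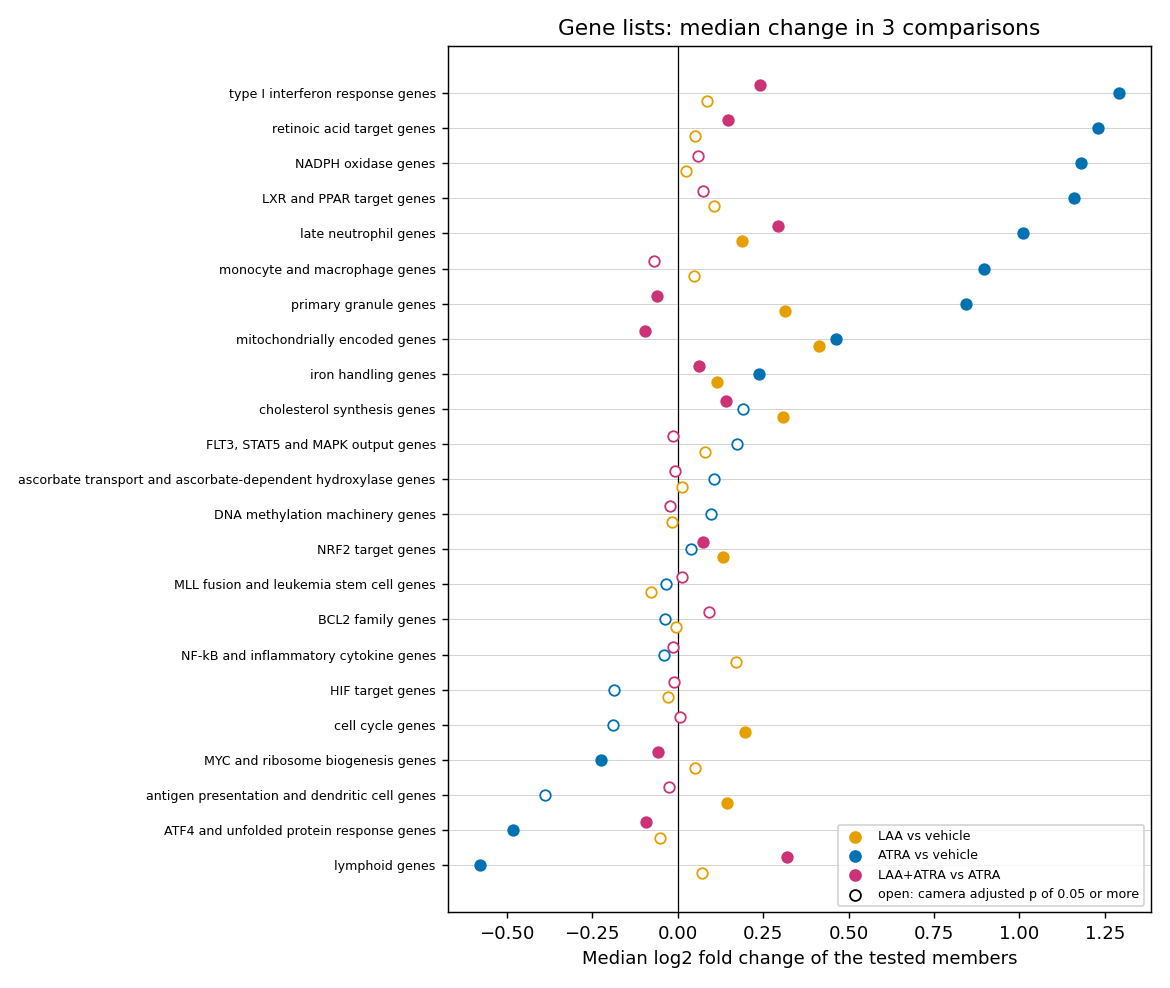
Median log2 fold change (horizontal axis) of the tested members of 23 gene lists (vertical axis) in LAA against vehicle, ATRA against vehicle and LAA+ATRA against ATRA; filled points have a camera adjusted p under 0.05 with the preset correlation, open points do not. Type I interferon response genes have a median of 1.29 with ATRA and of 0.24 in LAA+ATRA against ATRA, and cholesterol synthesis genes a median of 0.31 with LAA.

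Genes at which the combination lay beyond every other group were counted next. There were 29 that edgeR called with the same sign against vehicle, LAA and ATRA, 19 higher and 10 lower. The 19 included GALM, ALAS1, S100A8, S100A9, P2RY13, TFRC, FBXL5, CX3CR1, LINC03040 and TKT. The 10 included SLC7A5, VIM, MTHFD1L, AGRN, FLRT1 and FCER2. TKT, VIM, MTHFD1L and AGRN were named after their values were seen. The intermediate filament gene VIM had a mean of 553 CPM in vehicle, 607 in LAA, 139 in ATRA and 112 in LAA+ATRA. The count was 5 with the length offset, 104 with DESeq2, 207 when only the groups compared were fitted, and 12, 4 and 13 without LAA+ATRA replicates 5, 6 and 7.

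The combination was also compared with LAA alone, which asked whether ATRA acted in the presence of ascorbate as it did without it. TGM2 rose by 8.25 ± 0.17, DAAM2 by 9.05 ± 0.21, SIGLEC11, a sialic acid receptor gene, by 6.91 ± 0.18 and CD38 by 4.14 ± 0.07 (log2). IGLL1 fell by 7.59 ± 0.27, ASNS fell by 3.88 ± 0.30 and MYC fell by 1.45 ± 0.05. EdgeR called 8072 genes, 4073 higher and 3999 lower. TET2 (0.59 ± 0.18, edgeR adjusted p = 0.0121) and TET3 (0.45 ± 0.13, adjusted p = 0.0112) were higher in the combination than in LAA. Retinoic acid target genes (12 higher and 2 lower of 18; adjusted p = 8.75e-35; adjusted p = 0.00015 with an estimated correlation) and NADPH oxidase genes (6 of 6 higher; adjusted p = 2.28e-18; adjusted p = 0.00144 with an estimated correlation) were called by camera, with the same counts adjusted over the list alone. Cell cycle genes had 4 higher and 19 lower of 30 (4 and 20 adjusted over the list alone; camera adjusted p = 0.00086; adjusted p = 0.214 with an estimated correlation), with PLK1 at -0.75 ± 0.06 and AURKA at -0.66 ± 0.05. The ATRA effects without and with ascorbate share no library, and across the 16580 genes, which are not independent replicates, they had r = 0.715 and rho = 0.775. Of the 8210 genes called with ATRA alone, 8028 (97.8%) had the same sign with ascorbate present.

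The last comparison tested whether the ascorbate effect differed with and without ATRA. EdgeR called 9 genes, 2 with a more positive and 7 with a more negative effect on top of ATRA. The granule protease gene PRTN3 had the smallest p. Its ascorbate effect was 0.68 ± 0.07 alone and -0.29 ± 0.07 on ATRA, a difference of -0.97 ± 0.10 (edgeR adjusted p = 0.00143) that was called in 20 of 21 alternatives, the limit on size left aside. The other granule protease genes ELANE and CTSG differed by -0.57 ± 0.09 and -0.56 ± 0.09 (edgeR adjusted p = 0.0487 each), and GALM by 1.59 ± 0.26 (edgeR adjusted p = 0.049). ELANE was called in 7, CTSG in 8 and GALM in 10 of these 21 alternatives. PRTN3 (ENSG00000196415.10) and ELANE (ENSG00000197561.7) lie on chromosome 19 of GRCh38, from 840960 to 848175 and from 851014 to 856247, both on the plus strand. CTSG (ENSG00000100448.4) lies on chromosome 14 from 24573522 to 24576260 on the minus strand. The count of 9 was 169 with DESeq2, 3 with the length offset and with limma on FPKM, 33 without vehicle replicate 5, 39 without LAA replicate 7 and 15 without LAA replicate 5. It was 1 or 2 without vehicle replicate 6 or 7, LAA replicate 6, any ATRA library or LAA+ATRA replicate 5 or 6.

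Across genes, the ascorbate effects without and with ATRA, which share no library, had r = 0.063 and rho = 0.161. In 20 simulated data sets with an ATRA effect and no ascorbate effect r ranged from -0.051 to 0.076 and rho from -0.016 to 0.013. These simulations drew each gene independently and hold no trends across the genes of a library. Their ranges may therefore be too narrow, and they cannot decide whether the rho reflects a shared ascorbate effect. Of the 325 genes called with LAA alone, 233 (71.7%) had the same sign on top of ATRA. Called in both were 12 with the same sign (9 higher and 3 lower) and 1 with the opposite sign. Independent lists would share 0.336 higher and 0.101 lower. Of the 42 genes called on top of ATRA, 35 (83.3%) had the same sign with LAA alone. Genes are not independent replicates, so no p is given for these shares. LAA and ATRA alone, which share the vehicle libraries, both changed 252 genes, 210 in the same direction (160 higher and 50 lower) and 42 in opposite directions. Independent lists would share 57.8 higher and 22.9 lower. The covariance of their log2 fold changes was 0.173 against 0.0818 in simulated data without an ascorbate effect, a difference of 0.0913. The 3 vehicle libraries could not be split into parts of 2, so part of the excess over independent lists may come from the shared controls. The simulated data shared the vehicle libraries in the same way and gave 0 to 1 genes called in both with the same sign. They drew genes independently, so trends of a whole vehicle library are not covered and stay open. The 210 became 29 without vehicle replicate 7 and 709 without vehicle replicate 5.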

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

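The tests of low depth for LAA replicate 7, of that library alone for the mitochondrial genes and of scaling and of RLE factors for PRTN3, ELANE and CTSG were chosen after the results were seen.

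The ascorbate effect on top of ATRA differed from that without it at 9 genes by edgeR's test of the difference (n = 3 per group). The difference was -1.21 ± 0.20 for CPXM1, -0.971 ± 0.0993 for PRTN3, -0.566 ± 0.0905 for ELANE, -0.56 ± 0.0887 for CTSG, -0.537 ± 0.0776 for CHPF, -0.503 ± 0.0721 for MPI and -0.428 ± 0.0711 for SLC7A5 (log2, SE). It was 0.403 ± 0.0607 for ALAS1 and 1.59 ± 0.26 for GALM. Of CPXM1, PRTN3, ELANE, CTSG and MPI, each was called higher with ascorbate alone and none was called on top of ATRA. CHPF was called higher alone (0.25) and lower on ATRA (-0.28). SLC7A5 and GALM were called only on top of ATRA, and ALAS1 was called in both.

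Camera found a difference for 8 lists with the preset correlation and for 0 with an estimated one. The median difference of the primary granule genes was -0.302 (camera adjusted p = 3.56e-15; adjusted p = 0.11 with an estimated correlation). The medians were -0.178 for antigen presentation and dendritic cell genes, -0.187 for cell cycle genes, -0.0897 for MYC and ribosome biogenesis genes, -0.155 for cholesterol synthesis genes, -0.111 for ATF4 and unfolded protein response genes, -0.119 for FLT3, STAT5 and MAPK output genes and -0.493 for mitochondrially encoded genes. The camera adjusted p of the antigen presentation list was 0.0781 without vehicle replicate 5, 0.0533 without vehicle replicate 7, 0.0667 without LAA replicate 7 and 0.0583 without LAA+ATRA replicate 7. For the ATF4 list it was 0.16 without vehicle replicate 6, 0.0533 without vehicle replicate 7 and 0.0667 without LAA replicate 7. For the FLT3 list it was 0.164 without vehicle replicate 6, 0.144 without LAA replicate 7 and 0.0526 without LAA+ATRA replicate 6.

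Chance cannot be excluded for the number of genes with a different ascorbate effect: 11 of 100 splits of the libraries gave 9 genes or more, the real one included. The highest other split gave 304 genes and points to a structure of the samples, since it exchanges the ATRA and LAA+ATRA libraries and so sums the ascorbate effects without and with ATRA. The 9 remaining splits, with 11 to 53 genes, all set vehicle replicate 5 and LAA replicates 5 and 6 against vehicle replicates 6 and 7 and LAA replicate 7. That is also a structure of the samples: chi-square per degree of freedom was 23.8 and 25.8 between vehicle replicate 5 and the other vehicle libraries, against 6.69 between those, and 26.5 and 26.6 between LAA replicate 7 and the other LAA libraries, against 4.77 between those.

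LAA replicate 7 stood apart on the second principal component. Low depth as the reason is argued against by its total of 36 M counts, above the 35.6 M of LAA replicate 6. A yield that depends on GC content or transcript length stays open: across 16168 genes the rho of its deviation from the other LAA libraries was 0.182 with GC content and -0.278 with length, against sizes of up to 0.214 and 0.225 in other libraries. The gene length implied by the deposited tables deviated by over 10% for 32.5% of its genes, against 20.5% to 24.0% in the other libraries. No biological explanation was tested, since the labels give this library the same treatment as the other LAA libraries.

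Mitochondrially encoded genes were higher in LAA than in vehicle, with a median log2 fold change of 0.413. Vehicle replicate 5 alone is argued against by a median of 0.341 without it (median of the members' SE 0.0851), and a trend with GC content and length by a median of 0.393 after its removal. LAA replicate 7 as a main source stays open, since the median was 0.271 without it (median of the members' SE 0.0748). The limit of 0.2 set for the test lay within 1 such SE of that median. An effect of ascorbate on mitochondrial transcripts stays open and untested beyond this comparison, as does a difference in RNA yield or capture between libraries.

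The granule protease genes PRTN3, ELANE and CTSG rose with ascorbate alone and not on top of ATRA, with a mean difference of -0.699. LAA replicate 7 alone is argued against by a mean of -0.616 without it, and a trend with GC content and length by a mean of -0.639 after its removal. All 3 genes stayed called without LAA replicate 7 (edgeR adjusted p = 5.25e-05, 0.00889 and 0.00889) and without vehicle replicate 5, but ELANE and CTSG were not called with the length offset, with limma on FPKM, or without most other single libraries, and were called in 7 and 8 of 21 alternatives. The choice of TMM over RLE factors is argued against by a mean of -0.698 with RLE, where all 3 stayed called, but a shift of most genes, which both methods remove, stays open, since TMM itself sets the median difference over all genes (0.00302) near 0. A biological difference between cells with and without ATRA also stays open, as untested beyond this comparison.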

How the results depend on the processing

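The length offset, the omission of LAA replicate 7 from comparisons that do not use it and the list tests under the length offset and without libraries were chosen after results were seen. The cause was not tested for any change below, except where a setting asks for a larger change. The main fit shares the variance of each gene over all groups, although their spread differed. The median SD of log2 CPM within a group was 0.14 in vehicle and 0.16 in LAA. It was 0.09 in ATRA and 0.11 in LAA+ATRA. The SE and adjusted p of LAA against vehicle therefore borrow the tighter spread of the groups with ATRA. Those of LAA+ATRA against ATRA borrow the wider spread of the groups without ATRA.

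The counts for ATRA against vehicle, LAA+ATRA against vehicle and LAA+ATRA against LAA stayed within 1.5 times in every setting but the limit of a log2 fold change of at least 1, which left 1856, 2000 and 1812 genes. With that limit left aside, 4799, 4890 and 4683 genes were called in every alternative fitted for the comparison, against 1 in LAA against vehicle, 3 in LAA+ATRA against ATRA and 0 in the interaction. A gene that an alternative left untested counted there as not called.

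For LAA against vehicle (325) the counts were 942 with DESeq2, 1255 without a count filter, 1 with only the groups compared, 19 with the limit of 1, 28, 28 and 30 with limma on FPKM (pseudocount 1, 0.1, and 1 without a filter) and 13 with the length offset. For LAA+ATRA against ATRA (42) they were 177, 246 (117 higher and 129 lower), 418, 6, 13, 4, 17 and 7 in the same order, and 166 with LAA replicate 7 out of the shared fit. For genes beyond both single agents (29) they were 104, 126 (59 higher and 67 lower), 207, 5, 9, 3, 11 and 5. For the interaction (9), which always uses all groups, they were 169 with DESeq2, 241 without a filter (97 higher and 144 lower), 2 with the limit of 1, 3, 3 and 4 with limma on FPKM and 3 with the length offset. A fit of only the groups compared drops the variance shared over all groups. With it LAA against vehicle fell from 325 to 1, and LAA+ATRA against ATRA rose from 42 to 418. Both changes go in the direction of the difference in spread between the groups. The role of spread was not tested apart from the number of libraries.

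With the replicate number as a replicate block, 185 genes were called in LAA against vehicle, 1 in the interaction, and the overlap of the LAA and ATRA responses was 129 genes against 210. Residual correlation showed no pairing by number: r was -0.038 to 0.045 over 18 pairs of libraries with the same number and -0.064 to 0.058 over 36 pairs with different numbers. The deviation of replicate 7 had a GC rho of 0.182 in LAA, 0.166 in ATRA and 0.214 in LAA+ATRA, but -0.0423 in vehicle. Its length rho was -0.278, -0.156, -0.164 and 0.168 in the same order. A batch shared by some libraries of 1 number therefore stays open.

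Without 1 library, LAA against vehicle ran from 39 genes (vehicle replicate 7) to 1204 (vehicle replicate 5), and vehicle replicate 6 (84) and LAA replicate 6 (202) also changed it by over 1.5 times. LAA+ATRA against ATRA ran from 5 (LAA+ATRA replicate 6) to 16 (LAA+ATRA replicate 7), so that every one of its 6 libraries did. Genes beyond both ran from 4 to 13 without LAA+ATRA replicates 6 and 7, with 12 without replicate 5. The interaction ran from 1 (vehicle replicate 6) to 39 (LAA replicate 7), and every library but LAA+ATRA replicate 7 changed it by over 1.5 times. The overlap of LAA and ATRA ran from 29 (vehicle replicate 7) to 709 (vehicle replicate 5), and every library but LAA replicates 5 and 7 changed it by over 1.5 times.

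The correlation of the ascorbate effects, r = 0.063, was 0.120 with a filter of at least 1 CPM and ran from 0.037 without LAA+ATRA replicate 6 to 0.108 without ATRA replicate 5. Of 144 list tests 64 were called, 18 with an estimated correlation, 83 by fry, 59 with the length offset and 58 to 66 without a library.

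For the omission of single libraries, each result of a named gene was counted once per library left out of its comparison. Of these counts, 3031 kept their side of the threshold (called ones also their direction), 273 were no longer called and 14 were newly called. With the length offset, where each result counts once, the numbers were 441, 76 and 1, so they cannot be set directly against those for omitted libraries. CD36, LAA vs vehicle, was the result that reversed: -0.30 became 0.0187, 0.0189 and 0.0187 with limma on FPKM and 0.0274 with the length offset. CD14 and MPO, with 22 and 71 counts over all 12 libraries, were removed by the count filter, so changes in them were not tested.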

Other observations

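The test of whether the combination lies further along the ATRA response was chosen after the result was seen.

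Other splits of the libraries were counted for the comparisons of groups, where 10 splits of 6 libraries cannot give a share under 0.05. In each case 1 split, the real one, gave as many genes. For LAA against vehicle the real count was 325 and the highest other 177, from the split that sets vehicle replicate 5 and LAA replicates 5 and 6 against the rest. The real and highest other counts were 8210 and 0 for ATRA against vehicle, 8360 and 0 for LAA+ATRA against vehicle, 42 and 1 for LAA+ATRA against ATRA, 8072 and 1 for LAA+ATRA against LAA, and 29 and 0 for genes beyond both single agents.

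A hypothesis was that ascorbate moves ATRA-treated cells further along the ATRA response. Of the genes called with ATRA alone, 49.2% moved further in the same direction with the combination, against 42.3% to 44.4% in 20 simulated data sets with an ATRA effect and no ascorbate effect, where chance values in the shared ATRA libraries pull the share under 50%. The share was above every simulated one but not above the 50% set for the test. The simulated range may be too narrow, since genes were drawn independently, and 50% is not the share without an ascorbate effect. The test therefore cannot decide, and the hypothesis may hold for some genes and stays open. Of 35 genes called both with ATRA alone and in LAA+ATRA against ATRA, 23 moved the same way in both and 12 the opposite way.

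In 20 simulated data sets without any effect, the mean number of genes called was 0.2 for LAA against vehicle, 0.1 for LAA+ATRA against ATRA and 0.3 for the interaction. Genes were drawn independently in these sets too, so differences between whole libraries are not covered. Chi-square per degree of freedom between replicates ran from 3.66 to 26.6, so no pair of libraries agreed within sampling noise.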
